A study of Mus musculus with 8 samples.

How the data were processed

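Bulk RNA sequencing of 8 libraries was used, 4 from the iron positive eluate and 4 from the iron negative flowthrough of magnetic columns, each fraction with the tags 3L, 3R, 4R and 5L. Per the labels, the tumor digest was treated to lyse red cells before the columns, and libraries came from total RNA. Transcript abundances were made with kallisto 0.46.2 on the mouse build mm10, per the submitters' processing notes, and the release of the transcript set is not given in the sources used here. Each deposited table holds, per the file headers, estimated counts per transcript, which need not be whole and are not normalized, together with TPM values, which the authors' run scaled by effective length and library total, and the length and effective length of each transcript as other values. Each library has its own deposited table and no replicates were pooled.

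The 119414 transcripts of each table were joined to GENCODE release 21 for mouse (GRCm38, the same assembly as mm10) by transcript identifier without its version. Of these, 116728 matched and 2686 did not, and the latter held 0.888% to 0.961% of the estimated counts of a library. They were left out. Estimated counts were summed over the transcripts of each of 35975 genes and rounded to whole numbers for the tests. The sums do not use strand, so reads of genes that overlap on opposite strands cannot be told apart. Gene coordinates are those of the same annotation, counted from 1. Totals ranged from 19.04 to 24.31 M estimated counts per library, and the precision of each value is given as the SD over 4 libraries or the SE of the fold change.

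Genes were kept with filterByExpr, which left 13343, and libraries were scaled by the trimmed mean of M values (TMM). The main test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) on the fraction alone, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All p-values of single genes in the text come from it unless another tool is named. SEs are the absolute coefficient divided by the square root of the quasi-likelihood F, which is approximate. Levels are TMM-scaled CPM computed here, and log2 fold changes are iron positive minus iron negative. Gene lists were tested with camera of limma 3.58.1 on voom values, with the preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. None of the camera calls held with an estimated correlation, where the smallest adjusted p was 0.435 and 1 list had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move the same way on balance, called 8 lists: MHC class II, MHC class I presentation, immune checkpoints, mitochondrially encoded genes, NK cell, B and plasma cell, skeletal muscle, and iron uptake and sensing.

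Before the data were examined, 38 lists of 438 genes, an iron panel of 11 genes, the rule for named genes and most of the alternatives were fixed. The rule named the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold, with a mean of at least 5 CPM, the same direction in all 4 pairs and a symbol that is not a predicted, clone-like or pseudogene name. It further named the iron panel, and per list up to 3 members with the smallest adjusted p, or the 2 highest expressed members where none passed. Of the genes this rule picked, 3 are not reported here. Other members were named after their values were seen: Hfe, Prdx1, Nqo1, Axl, Fabp5, Spp1, Lpl, Trem2, Ctsl, Ciita, Lyz2, Cd68, Il1b, Tnf, Ccl4, Mgl2, Ankrd37, Vegfa, Ms4a4c and S100a9. Ero1a was matched under its older symbol and Ahsp was not found. Lists with fewer than 3 measured genes (4 of 38) were not tested as lists.

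Whether equal tags pair the libraries was checked by correlating, across genes, the deviations of libraries from their fraction's mean. Same-tag libraries correlated at 0.53 (3L), 0.52 (3R), 0.27 (4R) and 0.30 (5L), and each iron positive library correlated best with the iron negative library of its own tag (the highest other value was 0.26). The pairing comes from the shared tags in the labels. All 4 values lie above the limit of 0.1 set for it, so the fit with the tag as a block is given beside each result whose call it changes. No replicate pair agreed within counting noise: the chi-square per gene was 9.44 to 27.2 between iron negative and 43.9 to 112 between iron positive libraries.

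The steps were tested on simulated data. Counts were drawn for the 13343 genes from the observed means, library sizes and dispersions. Each gene was drawn independently and without a tag effect, unlike the data, so error rates in the data may differ. For the simulated comparison of iron positive and iron negative libraries, edgeR called 29 of 49 genes changed 2-fold, 44 of 48 changed 4-fold, 50 of 50 changed 8-fold and 50 of 50 changed 16-fold, none with the wrong sign, and 13 of 13001 unchanged genes. In a second draw, 2 of 34 lists were moved by 1 log2 unit with independent genes. Camera called both with the preset and 1 with an estimated correlation, and no unmoved list.

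The alternatives were DESeq2 1.42.0, limma voom, other scalings (relative log expression, library totals, the macrophage list), no filter or a minimum of 5 CPM in 4 libraries, the tag as a block, average transcript length offsets, limma on log2(TPM + 1) and log2(TPM + 0.1), removal of erythroid, immunoglobulin and mitochondrial genes, a test against 1.5-fold, and leaving out libraries singly or by tag. The macrophage scaling was fixed beforehand for the iron panel and other named genes, and was chosen after the data were seen for the counts of genes and the list tests. Camera without the stromal and muscle lists and the fit on tags 3L and 5L alone were also chosen then. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the join and the plots.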

Results

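Subcutaneous fibrosarcomas grown from syngeneic cells in wild-type C57BL/6 mice were digested to single cells and passed over magnetic columns. Cells that the column held formed the iron positive eluate, and cells that passed through formed the iron negative flowthrough. RNA from both fractions was sequenced in bulk. The 8 libraries comprised 4 iron positive and 4 iron negative ones, and each tag (3L, 3R, 4R and 5L) occurred once in each fraction. The series title speaks of macrophages, but the labels name no antibody sort, so other tumor cells could enter either fraction. Estimated counts totalled 19.04 to 24.31 M per library. The iron negative libraries held 24.31 (3L), 20.6 (3R), 22.33 (4R) and 23.94 (5L) M, and the iron positive ones 20.9 (3L), 19.04 (3R), 22.31 (4R) and 22.59 (5L) M. The labels do not say whether the tags come from separate animals, so the p-values measure the spread between these samples. The comparison asks which transcripts differ between cells that are magnetically retained, a property of iron-loaded cells, and cells that passed through. In the iron negative libraries the macrophage genes Csf1r and Adgre1 averaged 2766 and 1057 CPM. Sparc, a fibroblast and fibrosarcoma marker, averaged 36.6 and Vwf, an endothelial marker, 4.49 CPM. Fold changes of such markers therefore start from low levels in a fraction rich in macrophage transcripts.

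Vascular genes were among the largest increases in the iron positive fraction, and MHC class II genes among the largest decreases. Of 13343 genes tested, 1133 were higher and 695 lower in the iron positive libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The increases were large, with a median log2 fold change of 2.35, 881 genes above 2-fold and 221 above 16-fold. The decreases were small, with a median log2 fold change of -0.37 and only 15 genes beyond 2-fold. The genes named next were ranked among those with a mean of at least 5 CPM and the same direction in all 4 same-tag pairs, so larger changes of weakly expressed genes are not shown. Gja5, a connexin of arterial endothelium, went from 0.22 ± 0.16 to 19.4 ± 18.4 CPM (library-scaled counts; mean ± SD, n = 4), a log2 fold change of 6.45 ± 0.98 (SE) with adjusted p = 0.0173. The next largest increases were those of Inhbb (6.24), Crispld2 (6.15), Nova2 (6.09), Grrp1 (6.04), Gja4 (5.97), Lama5 (5.95), Dysf (5.94), Dll4 (5.93), Sox17 (5.91), Ptprb (5.89) and Bcam (5.85), all as log2 fold changes. Dll4 is a Notch ligand of sprouting and arterial endothelium, Sox17 an arterial transcription factor, Ptprb the vascular endothelial tyrosine phosphatase and Lama5 a basement membrane laminin chain. Cd74, the invariant chain of MHC class II, had the largest decrease within those limits, at -1.19 ± 0.24 (6332 ± 1314 to 2785 ± 801 CPM, adjusted p = 0.0203). It was followed by Capn3 (-1.17), H2-Eb1 (-1.12), Tlr12 (-1.12), H2-Aa (-1.12), Lag3 (-1.08), H2-Ab1 (-1.07), Ighm (-1.03), Dnase1l3 (-1.01), Siglece (-0.998), Tmem176a (-0.99) and Lilra5 (-0.99). Of all called genes, 1128 of the 1133 higher and 694 of the 695 lower ones moved the same way in all 4 pairs.

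The number of calls depended on the fit, the scaling and single libraries. With the tag as a block, 1705 genes were higher and 1253 lower, of which 1118 and 667 were shared with the fit without it. Scaling by library totals gave 1172 higher and 362 lower genes (76.4% higher, against 62% with TMM). Scaling to the macrophage list moved the median of all genes by 0.294 log2 units and gave 3198 higher and 36 lower genes (98.9% higher). Under that scaling 195 of the 695 genes called lower with TMM turned to a positive fold change, and no gene called higher turned. No gene passed in edgeR without iron negative 3L, 3R or 4R, where the smallest adjusted p was 0.0619, 0.0511 and 0.063. At an unadjusted p under 0.05 those fits gave 2066, 2145 and 2103 higher and 1490, 1452 and 1601 lower genes, and DESeq2 on the same libraries called 1418, 1537 and 1455 higher and 743, 755 and 746 lower. Without iron negative 5L, 26 genes were higher and 12 lower. Without iron positive 4R, 399 were higher and 214 lower. In each of these fits without a library all 1828 called genes kept their direction. They were called on all libraries, most of which each fit reuses, so a change of direction was unlikely from the start.

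Of the 11 genes of the iron panel, 5 rose in the iron positive libraries, 4 of heme and iron handling and 1 endothelin receptor, and none fell (6 passed when adjusted over the list alone). The iron positive libraries differed widely in these genes. Hmox1, which encodes the enzyme that opens the heme ring and frees its iron, lies on chromosome 8 at 75093621 to 75100589 (mm10). It went from 654 ± 169 to 2890 ± 2150 CPM (n = 4 per fraction), a log2 fold change of 2.14 ± 0.58 with adjusted p = 0.0428. Its iron positive values were 5174 in 3L, 4230 in 4R, 1455 in 5L and 700 CPM in 3R. Slc40a1, the iron exporter ferroportin (chromosome 1, 45908068 to 45926523), rose by 3.02 ± 0.56 log2 units, from 47.6 ± 20.6 to 386 ± 286 CPM (adjusted p = 0.0183). Slc48a1, a transporter of heme out of the phagolysosome, rose by 1.66 ± 0.39 (69.1 ± 3.4 to 218 ± 125 CPM, adjusted p = 0.029). Cd163, the receptor for hemoglobin bound to haptoglobin, rose by 2.22 ± 0.58 (20.8 ± 6.4 to 96.9 ± 82.8 CPM, adjusted p = 0.0398). Ednrb, an endothelin receptor on chromosome 14 (103814625 to 103844402), had the largest change of the panel at 4.95 ± 0.81 (2.54 ± 1.38 to 79.1 ± 65 CPM, adjusted p = 0.0173).

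The ferritin genes did not pass with TMM, but they did under the macrophage scaling, where Ftl1 stood at 0.98 (adjusted p = 0.0207) and Fth1 at 0.73 (adjusted p = 0.032). With TMM, Ftl1 had a log2 fold change of 0.72 ± 0.29 (5512 ± 508 to 9084 ± 3959 CPM, adjusted p = 0.129) and Fth1 one of 0.46 ± 0.25 (5096 ± 602 to 7006 ± 2587 CPM, adjusted p = 0.258), each higher in 3 of 4 pairs. Reads of both can be shared with processed pseudogenes, so their levels are uncertain. Spic, a transcription factor of heme-recycling macrophages (0.59, adjusted p = 0.294), Blvrb, a biliverdin reductase (0.32, adjusted p = 0.258), Tfrc, the transferrin receptor (0.23, adjusted p = 0.0683), and Bach1, a heme-sensing repressor (-0.09, adjusted p = 0.558), did not pass either. Tfrc was higher in all 4 pairs and passed when adjusted over the panel alone (adjusted p = 0.0215), besides the panel genes called over all genes. Bach1 had a positive value, 0.20, under the macrophage scaling. Scaled that way, 9 panel genes were higher, among them Blvrb (0.59, adjusted p = 0.0208) and Tfrc (0.52, adjusted p = 0.0138). With any iron negative library left out no panel gene passed in edgeR (6 at an unadjusted p under 0.05 in each case), and 2 passed without iron positive 4R. Hmox1 also lost its call without iron positive 3L (adjusted p = 0.0742) or 4R (0.109).

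**Figure D1:**
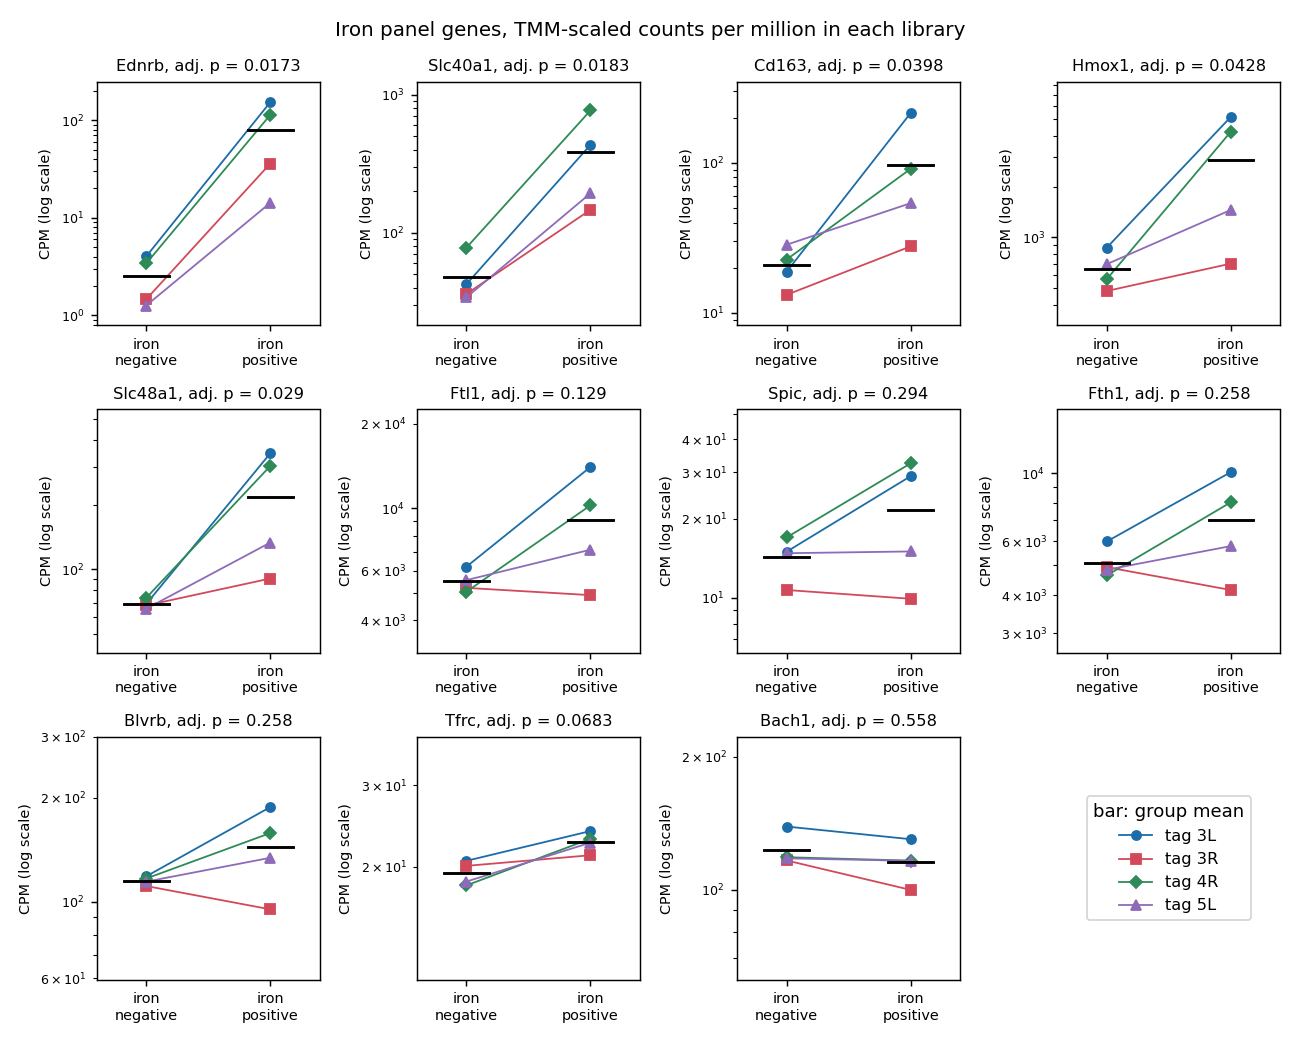
CPM (log axis) of the 11 iron panel genes in the 4 iron negative and 4 iron positive libraries, with a line joining libraries of the same tag and a black bar at each group mean. Ednrb, Slc40a1, Cd163, Hmox1, Slc48a1 and Tfrc were higher in all 4 pairs and Bach1 was lower in all 4, whereas Ftl1, Fth1, Spic and Blvrb were higher in 3 of 4 and lower in tag 3R.

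In the wider list of heme and iron recycling, 4 of 15 measured genes rose (Hmox1, Slc40a1, Slc48a1 and Cd163) and Hfe fell. With adjustment over the list alone 5 were higher and 1 lower. Under the macrophage scaling 11 were higher, none was lower in edgeR and Hfe turned to 0.01 (adjusted p = 0.939). The list ranked as higher (median log2 fold change 0.42, camera adjusted p = 0.0145), and adjusted p = 0.51 with an estimated correlation. It was no longer called without iron positive 3L (camera adjusted p = 0.121). Among 12 genes of iron uptake and sensing, 3 rose: Steap4 (5.62 ± 0.85), a metalloreductase, Slc25a37 (0.75 ± 0.15), the mitochondrial iron importer mitoferrin, and Slc39a14 (0.40 ± 0.11; adjusted p = 0.0501 with the tag as a block). That list was not called (camera adjusted p = 0.15; 5 higher and 1 lower when adjusted over the list alone, 3 higher and 1 lower with the block, 6 higher under the macrophage scaling). Steap4 averaged only 0.08 CPM in the iron negative libraries. Its iron positive values, 1.30 (3L), 6.60 (3R), 6.85 (4R) and 1.89 CPM (5L), were lowest in 3L, where Hmox1 was highest. Of 16 genes listed as antioxidant targets of NRF2 and BACH1 5 rose, namely Me1 (1.91 ± 0.36), Gclm (2.22 ± 0.44), Gsr (2.04 ± 0.42), Prdx1 (1.30) and Nqo1 (1.35). Gclm encodes the modifier subunit of the enzyme that starts glutathione synthesis, and Gsr glutathione reductase. Adjusted over the list alone 10 were higher, with the block 8 and under the macrophage scaling 14. The count was 3 on either TPM scale, and 0 with limma voom or against 1.5-fold. Camera gave adjusted p = 0.000153, and adjusted p = 0.435 with an estimated correlation. Of the endothelin genes, Ednrb, Ednra (3.61 ± 0.79) and Edn1 (3.30 ± 0.50) rose, 3 of the 5 genes listed with Bach1 (4 adjusted over the list alone, 4 with the block; camera adjusted p = 0.0445, adjusted p = 0.435 with an estimated correlation). That call was lost without iron negative 3R, 4R or 5L (adjusted p = 0.0581, 0.0798 and 0.0752), and under the macrophage scaling (camera adjusted p = 0.0947, with 4 genes higher). Ednra (1.45 CPM in iron positive 3L, 16.5 in 3R, 9.42 in 4R and 2.42 in 5L) and Edn1 (5.88, 33.2, 26.6 and 13.6 CPM) were highest in 3R and lowest in 3L, as was the mean of the called endothelial and mural markers, and unlike Hmox1. None of the 9 ferroptosis-related genes passed over all genes (5 higher when adjusted over the list alone). With the block 3 were higher and 1 lower, and under the macrophage scaling 6 were higher. Their highest expressed members were Gpx4 (0.19, adjusted p = 0.0867; 0.48, adjusted p = 0.011 under the macrophage scaling) and Ptgs2 (-0.24, adjusted p = 0.678; lower with the block at adjusted p = 0.0156, and 0.02 under the macrophage scaling). Camera still called that list higher (adjusted p = 0.0233), with adjusted p = 0.435 with an estimated correlation, 0.0653 with the block and 0.111 without iron positive 3L. With any iron negative library left out no gene of these 5 lists passed in edgeR. Without iron positive 4R, 1 heme, 1 NRF2 and 1 iron uptake gene were higher, and without iron positive 3L 2 iron uptake genes. Without iron positive 3R, 8 heme, 8 NRF2 and 4 ferroptosis-related genes were higher. Hfe did not pass without iron positive 3L, 3R or 4R. Nor was it called lower with limma voom, relative log expression, library totals, length offsets, either other filter or either TPM fit. DESeq2 and the block each kept 1 lower gene in its list.

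Receptors for modified lipids and lipid-handling genes included some of the steepest rises outside the vascular lists. Of 11 scavenger receptors 4 rose, Marco (5.03 ± 0.73, 0.61 to 20.2 CPM), Cd36 (4.17 ± 0.58, 17.6 to 317 CPM), Colec12 (1.90 ± 0.19) and Cd163, and Axl fell (-0.77), with the same counts adjusted over the list alone. Axl did not pass under the macrophage scaling (-0.47, adjusted p = 0.094). The list was not called (camera adjusted p = 0.126; 0.0305 without iron positive 3R). Of 15 lipid-associated macrophage genes 7 rose (7 adjusted over the list alone, 12 under the macrophage scaling), among them Fabp4 (4.78 ± 0.64), a fatty acid binding protein that capillary endothelium also expresses, Gpnmb (3.78 ± 0.54), Cd36, Fabp5 (1.96), Spp1 (1.94), Ctsd (0.87) and Lpl (0.71). Trem2, the lipid-sensing receptor of such macrophages, did not pass with TMM (0.10, adjusted p = 0.569) but was higher under the macrophage scaling (0.37, adjusted p = 0.0149). Of the 7 called lipid-associated genes 6 were higher in iron positive 3L than in 3R, and 1, Fabp4, was higher in 3R. Fabp4 stood at 29.3 (3L), 117.5 (3R), 115.8 (4R) and 23.9 CPM (5L). It was thus higher in 3R and 4R than in 3L and 5L, as was the mean of the called endothelial and mural markers. Camera gave the lipid-associated list adjusted p = 0.000315, and adjusted p = 0.435 with an estimated correlation. Lysosomal genes went both ways, which depended on the scaling. Atp6v0d2, a proton pump subunit (1.85 ± 0.39), Ctsd and Ctsl (1.17) rose and 1 gene fell, 4 of 16 past the threshold (4 higher and 3 lower adjusted over the list alone, and the same with the block). Under the macrophage scaling 9 were higher and none lower in edgeR, and the median went from 0.04 to 0.32. The list was not called (camera adjusted p = 0.933). Without iron negative 5L, 1 scavenger receptor of these lists passed in edgeR, and without iron negative 3L, 3R or 4R no gene did. Without iron positive 4R, 3 lipid-associated and 1 lysosomal gene were higher, and without iron positive 3L 1 lysosomal gene was higher and 2 were lower.

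Endothelial transcripts were scarce in the iron negative libraries and rose in every iron positive library. All 13 endothelial markers were higher, with a median log2 fold change of 4.95. Vwf, the von Willebrand factor, rose by 4.30 ± 0.72 (4.49 ± 1.45 to 88.1 ± 77.1 CPM, adjusted p = 0.0173), Kdr, the main VEGF receptor, by 4.04 ± 0.70, and Tie1, an endothelial receptor kinase, by 5.41 ± 0.94. Of 11 pericyte and smooth muscle markers 8 rose (median 4.69; 10 with the tag as a block), including Des (5.30 ± 0.62), Myh11 (5.30 ± 0.86) and Notch3 (5.56 ± 0.96). Of 12 fibroblast and fibrosarcoma markers 7 rose (median 2.67; 11 with the tag as a block), with Sparc at 3.99 ± 0.85 (36.6 ± 23.4 to 582 ± 577 CPM), Postn at 3.07 ± 0.75 and Fbn1 at 2.94 ± 0.78. All 7 measured skeletal muscle markers rose (median 3.64), with Acta1 at 4.48 ± 0.50 (0.80 ± 0.52 to 17.8 ± 8.4 CPM) and Tnnt3 at 4.05 ± 0.63. Adjusted over the list alone, 13, 10, 11 and 7 genes of these lists were higher. Camera called all 4 higher, with adjusted p = 6.25e-05 for endothelial, 0.000255 for pericyte, 0.000312 for fibroblast and 1.01e-05 for muscle markers, and adjusted p = 0.435 with an estimated correlation for each. The fibroblast list was not called under the macrophage scaling (camera adjusted p = 0.0799), although 10 of its genes were higher. Vwf stood at 186 CPM in 3R, 114 in 4R, 29.7 in 5L and 23.3 in 3L, while Hmox1 was highest in 3L and lowest in 3R. Leaving out any iron negative library left at most 1 gene per list past the threshold, although 13 endothelial markers stayed under an unadjusted p of 0.05. Without iron positive 4R, 7 endothelial, 5 pericyte, 5 muscle and 0 fibroblast markers passed in edgeR, with 11 of the fibroblast markers at an unadjusted p under 0.05. The fibroblast count was 11 without iron positive 3L, 4 without 3R and 10 without 5L. On the tags with the lowest vascular values, 3L and 5L, 321 genes were higher and 7 lower.

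**Figure D2:**
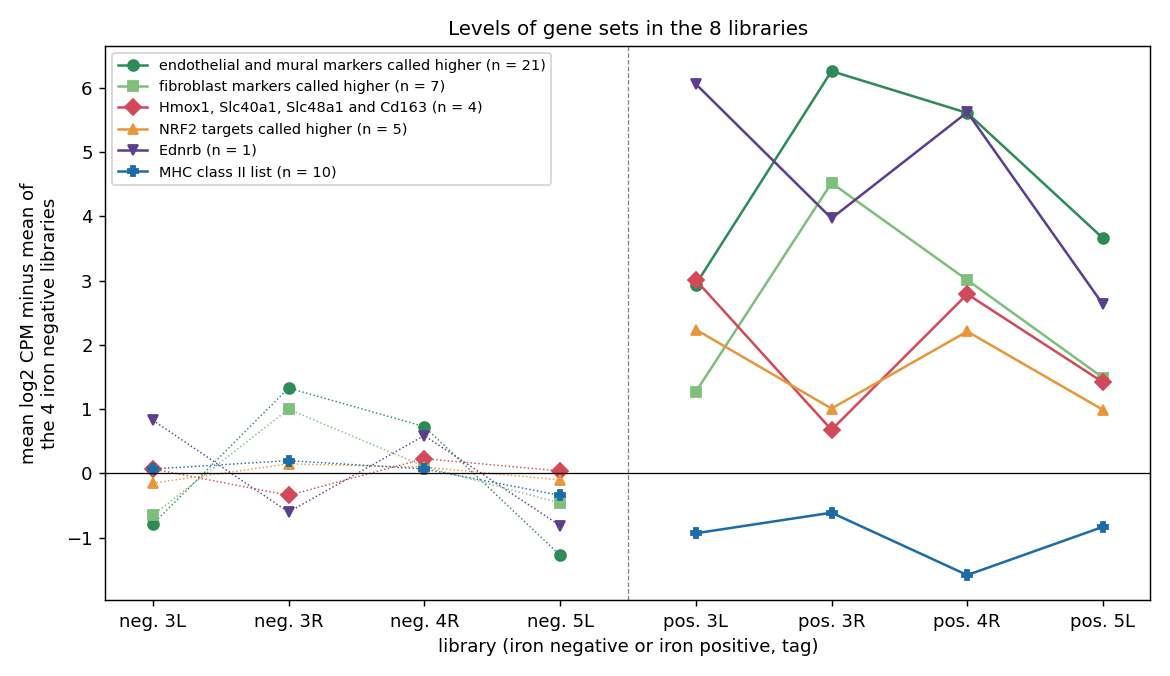
Mean log2 CPM of sets of genes in each of the 8 libraries, less the mean of the 4 iron negative libraries. Endothelial and mural markers peaked in iron positive 3R (6.26) and the set of Hmox1, Slc40a1, Slc48a1 and Cd163 in 3L (3.01), where Ednrb also peaked (6.06).

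**Figure D3:**
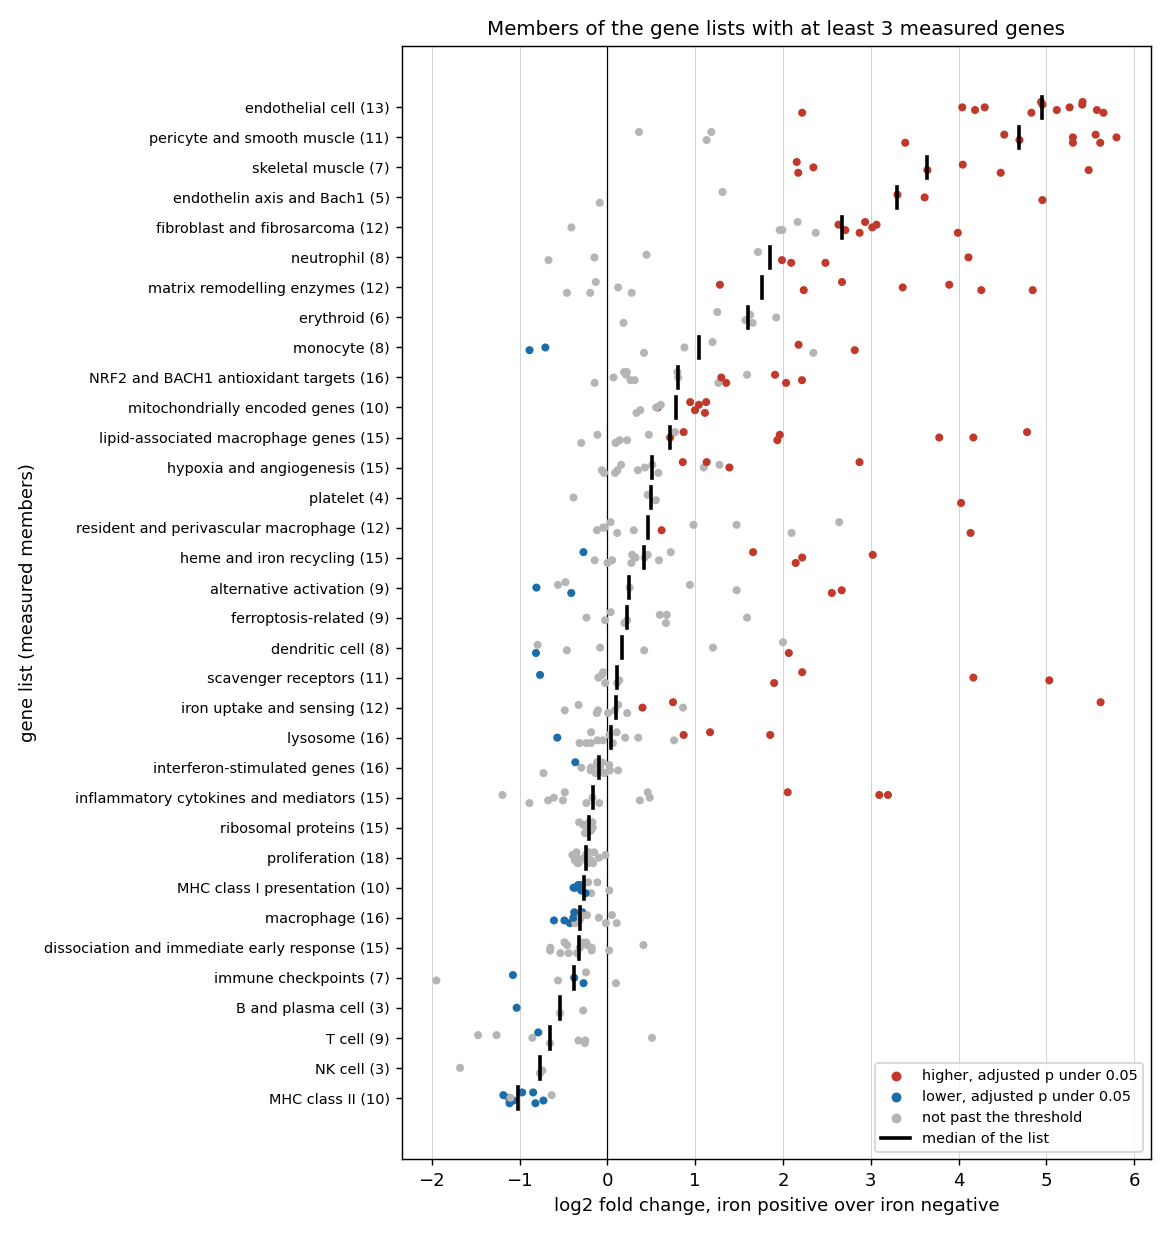
Log2 fold change (iron positive over iron negative) of every measured member of the 34 gene lists with at least 3 measured genes, with red and blue points for genes past the threshold and a black bar at each list's median. Endothelial, pericyte and skeletal muscle lists lie farthest to the right, with medians of 4.95, 4.69 and 3.64, and the MHC class II list farthest to the left at -1.02; under the macrophage scaling the bars of the MHC class I, interferon, cytokine, proliferation and ribosomal lists change sign.

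MHC class II genes fell together. All 10 had a negative fold change (median -1.02; -0.71 under the macrophage scaling) and 8 passed the threshold, 10 when adjusted over the list alone, 9 with the block and 3 under the macrophage scaling. Of the list's genes past the threshold, the class II chains H2-Eb1 (2036 ± 489 to 935 ± 261 CPM), H2-Aa (1883 ± 427 to 870 ± 242 CPM) and H2-Ab1 (2352 ± 546 to 1119 ± 309 CPM) fell most after Cd74. The peptide loading genes H2-DMa (-0.85 ± 0.14), H2-DMb1 (-0.82 ± 0.16) and H2-DMb2 (-0.73 ± 0.12) fell less, and Ciita, the master activator of the class II genes, fell by 0.97 on the log2 scale. Camera gave the list adjusted p = 5.07e-07, and adjusted p = 0.435 with an estimated correlation. Of 10 genes of MHC class I presentation 6 fell (8 adjusted over the list alone, 7 with the block; median -0.27, which turned to 0.02 under the macrophage scaling), with Psmb9 at -0.39 ± 0.08, Psmb10 at -0.31 ± 0.07 and Tapbp at -0.25 ± 0.05 (camera adjusted p = 6.25e-05; adjusted p = 0.435 with an estimated correlation). Of 16 macrophage markers 6 fell (9 adjusted over the list alone, 11 with the block; median -0.31), including Csf1r, the receptor for macrophage colony-stimulating factor (-0.61 ± 0.11, 2766 ± 84 to 1814 ± 246 CPM), Adgre1, a surface receptor of mature macrophages (-0.43 ± 0.08), and Ms4a7 (-0.38 ± 0.08). Lyz2 (9951 to 10710 CPM, adjusted p = 0.67; 0.38, adjusted p = 0.0296 under the macrophage scaling) and Cd68 (adjusted p = 0.66) did not pass. That list was called lower (camera adjusted p = 6.25e-05; adjusted p = 0.435 with an estimated correlation). Of 7 immune checkpoint genes, Lag3 (24.6 ± 3.1 to 11.7 ± 3 CPM), Havcr2 (-0.38 ± 0.09) and Vsir (-0.27 ± 0.07, but 0.02 under the macrophage scaling) fell, 3 in all, 4 adjusted over the list alone and 4 with the block (camera adjusted p = 0.0146; adjusted p = 0.435 with an estimated correlation). Under the macrophage scaling the 3 class II genes, 1 macrophage gene and 1 checkpoint gene were the only members of these lists still lower. None of the genes of these 4 lists passed in edgeR with any iron negative library left out, where at least 9 MHC class II and 8 macrophage genes had an unadjusted p under 0.05. Without iron positive 4R, 5 MHC class II, 1 class I, 2 macrophage and 1 checkpoint gene passed. The class I count was 3 without iron positive 3L, and the checkpoint count 2 without iron positive 3L and 1 without 3R.

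Cytokine and polarization genes did not move as blocks. Of 15 inflammatory genes, Il6 (3.10 ± 0.39, 1.02 ± 0.26 to 8.79 ± 4.24 CPM), Cxcl3 (3.20 ± 0.77), a neutrophil-attracting chemokine, and Nos2 (2.05 ± 0.48), the inducible nitric oxide synthase, rose (3 adjusted over the list alone). With the tag as a block 4 were higher and 7 lower, among the latter Il1b, Tnf and Ccl4 (adjusted p = 0.0124, 0.00389 and 0.00202). The list was not called with TMM (camera adjusted p = 0.876; median -0.17, mean 0.32). Camera called it lower under the macrophage scaling (adjusted p = 0.00695), although its median was then 0.09 and 5 of its genes were higher and none lower in edgeR. Of 9 alternative activation genes, Arg1, the arginase of these cells (2.56 ± 0.55, 214 ± 44 to 1258 ± 881 CPM), and Ccl24 (2.67 ± 0.67) rose, and Tgfb1 (-0.41 ± 0.07) and Mgl2 (-0.81) fell, with the same counts adjusted over the list alone and 2 higher and 3 lower with the block (camera adjusted p = 0.933). Neither decrease passed under the macrophage scaling, where 3 genes were higher (-0.12 and -0.51, adjusted p = 0.204 and 0.113 for Tgfb1 and Mgl2). Of 12 matrix remodelling genes 7 rose (7 adjusted over the list alone; 7 higher and 1 lower with the block), led by Adamts1 (4.84 ± 0.78), Mmp9 (3.36 ± 0.55, 31 ± 10.8 to 320 ± 219 CPM) and Timp1 (2.24 ± 0.39) (camera adjusted p = 0.0145; adjusted p = 0.435 with an estimated correlation and 0.115 under the macrophage scaling). Of those 7 genes 5 were higher in iron positive 3R than in 3L, as were all called endothelial and fibroblast markers (median log2 of 3L over 3R -2.75, against -3.22 and -3.26). Adamts1 stood at 305 CPM in 3R and 41.4 in 3L. Of 15 hypoxia and angiogenesis genes 4 rose (8 adjusted over the list alone, 7 with the block, 11 under the macrophage scaling), with Adm, the vasodilator adrenomedullin, at 2.87 ± 0.49, Egln3, an oxygen sensor, at 1.39 ± 0.33, Ddit4 at 1.13 ± 0.30 and Ankrd37 at 0.86. In the iron positive libraries Adm stood at 7.33 (3L), 28.7 (3R), 13.9 (4R) and 6.82 CPM (5L), highest in 3R like the endothelial and mural mean. Of the 4 called hypoxia genes 3 were higher in 3R than in 3L and 1 was higher in 3L. Vegfa did not pass (0.09, adjusted p = 0.894). Camera called that list higher (adjusted p = 0.000458; adjusted p = 0.435 with an estimated correlation). With any iron negative library left out no gene of these 4 lists passed in edgeR, and 1 inflammatory, 1 alternative activation, 5 matrix and 1 hypoxia gene passed without iron positive 4R. Without iron positive 3R, 5 inflammatory and 2 hypoxia genes were higher. Without iron positive 3L, 2 hypoxia genes were higher, and 1 alternative activation gene was higher and 1 lower. Without iron positive 5L, 7 hypoxia and 3 alternative activation genes were higher and 2 inflammatory genes lower.

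Markers of other blood cells gave mixed results. In the resident and perivascular macrophage list 2 of 12 genes rose (5 adjusted over the list alone, 6 with the block and 6 under the macrophage scaling), Gas6 (0.62 ± 0.17) and the lectin gene Cd209g (4.14 ± 1.15), the latter carried by 3L, at 4.89 CPM against 0.53 to 0.76 in the other iron positive libraries. Camera called the list higher (adjusted p = 0.0407; adjusted p = 0.51 with an estimated correlation), and only the fits without iron negative 5L or iron positive 3R kept that call (adjusted p = 0.0507 to 0.115 in the others). Of 8 monocyte genes F10 (2.82 ± 0.56) and Vcan (2.18 ± 0.49) rose, and Ccr2, the chemokine receptor of inflammatory monocytes (-0.89 ± 0.18, 208 ± 16 to 112 ± 28 CPM), and Ms4a4c (-0.71) fell (camera adjusted p = 0.295; 4 higher and 2 lower adjusted over the list alone and with the block, 4 higher and 1 lower under the macrophage scaling). Ms4a4c did not pass under that scaling (-0.43, adjusted p = 0.0596). Of 8 neutrophil genes 4 rose (5 adjusted over the list alone; 5 higher and 1 lower with the block), Mmp8 (4.11 ± 0.78), S100a8 (2.48 ± 0.52), S100a9 (1.99) and G0s2 (2.09 ± 0.44). In the iron positive libraries Mmp8 averaged 25.6 and S100a8 6.91 CPM. That list was called higher (camera adjusted p = 0.0412; adjusted p = 0.435 with an estimated correlation), though not without iron negative 3R or 5L or iron positive 3L (adjusted p = 0.0581, 0.101 and 0.109), nor under the macrophage scaling (0.173). Of 8 dendritic cell genes Zbtb46 rose (2.07 ± 0.48) and Batf3 fell (-0.81 ± 0.22) (camera adjusted p = 0.563; 3 higher and 1 lower adjusted over the list alone, 2 higher and 1 lower with the block). Batf3 did not pass under the macrophage scaling (-0.54, adjusted p = 0.11), where 3 dendritic cell genes were higher. Kit (3.42 ± 0.74) and Hdc (1.34 ± 0.36), the only measured mast cell and basophil genes, both rose (2 adjusted over the list alone). In iron positive 3L, 3R, 4R and 5L, Kit stood at 3.74, 32.9, 11.3 and 4.31 CPM and Zbtb46 at 2.14, 7.86, 7.28 and 2.95. Vcan stood at 16.2, 46.1, 24.85 and 9.51 CPM in the same order. Kit, Zbtb46 and Vcan thus peaked in 3R, as did the mean of the endothelial and mural markers, whereas Hdc was highest in 3L (3.79 CPM). None of the genes of these 5 lists passed in edgeR with any iron negative library left out. The 2 resident macrophage genes became 0 without iron positive 3L or 4R in edgeR (5 and 6 at an unadjusted p under 0.05) and 4 without 3R, and the 4 neutrophil genes became 1 without 4R. Among monocyte genes 1 was higher and 1 lower without 4R, 1 was lower without 3L or 3R and 3 were higher without 5L. Kit and Hdc did not pass without iron positive 4R, and 1 of them passed without 3L. Of the dendritic cell genes 2 were higher without 3L, none was higher without 4R in edgeR (2 at an unadjusted p under 0.05) and none lower without 3R in edgeR (1 at an unadjusted p under 0.05).

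Cd4 fell (31.9 ± 5.1 to 18.5 ± 2.7 CPM, log2 fold change -0.79 ± 0.14), and it was the only 1 of 9 T cell genes past the threshold (1 adjusted over the list alone, 3 with the block), but it did not pass under the macrophage scaling (-0.50, adjusted p = 0.071). The T cell list was not called (camera adjusted p = 0.0517), but it was called with the block (0.0331) and without iron negative 3L or 5L or iron positive 3R or 4R (0.0123, 0.0205, 0.0423 and 0.0335). It was also called lower under the macrophage scaling (camera adjusted p = 4.18e-06), where none of its genes passed in edgeR. With an estimated correlation it had adjusted p = 0.435. Of 3 NK cell genes none passed over all genes (2 adjusted over the list alone, 1 with the block). Gzmb (-1.68 ± 0.48, adjusted p = 0.0509; 0.0206 with the block) and Klrk1 (-0.74 ± 0.22, adjusted p = 0.0557) came closest. The list was called lower (camera adjusted p = 0.0329; adjusted p = 0.435 with an estimated correlation), with adjusted p = 0.0546 with the block, 0.0524 without iron positive 3L and 0.0531 without iron positive 5L. Of 3 B and plasma cell genes Ighm fell (60.9 ± 8.8 to 29.7 ± 6.7 CPM; 1 adjusted over the list alone), and the list was called lower (camera adjusted p = 0.0341; adjusted p = 0.435 with an estimated correlation), with adjusted p = 0.0744 with the block and 0.0514 and 0.0839 without iron positive 3L and 3R. Of 4 platelet genes only Ppbp, a chemokine that macrophages can also express, rose (4.03 ± 0.88, 11.7 ± 4.9 to 191 ± 172 CPM; 1 adjusted over the list alone; camera adjusted p = 0.282). Hemoglobin transcripts were higher in all 4 pairs but did not pass: Hbb-bs went from 11 ± 10 to 41.6 ± 36 CPM (adjusted p = 0.106; 0.00028 with the block) and Hba-a2 from 8.76 ± 5.62 to 26 ± 21.3 CPM (adjusted p = 0.132; 0.00262 with the block). No erythroid gene of 6 measured passed (none adjusted over the list alone), 4 passed with the block, and camera called the list higher (adjusted p = 0.0131; adjusted p = 0.435 with an estimated correlation and 0.173 under the macrophage scaling). Alpha and beta globin copies share reads, so single globin genes are uncertain. Ppbp did not pass without iron positive 4R, and no gene of these 5 lists passed in edgeR with any iron negative library left out.

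Of 10 mitochondrially encoded genes 6 rose (10 adjusted over the list alone, 7 with the block; median 0.78). All 10 were higher under the macrophage scaling, with a median of 1.08. Those with the smallest adjusted p were mt-Nd2 (1.11 ± 0.20), mt-Nd1 (0.94 ± 0.18) and mt-Co3 (0.57 ± 0.11) (camera adjusted p = 1.26e-06; adjusted p = 0.435 with an estimated correlation). None of 15 ribosomal protein genes passed (none adjusted over the list alone, 4 lower with the block). Their medians were -0.21 and, under the macrophage scaling, 0.09, with Rplp0 at -0.21 and 0.09 and Rpl4 at -0.19 and 0.11, and camera called the list lower (adjusted p = 6.95e-05; adjusted p = 0.435 with an estimated correlation). No proliferation gene of 18 passed (none adjusted over the list alone, 6 lower with the block, Top2a among them at adjusted p = 0.0362). Top2a had a value of -0.37 ± 0.14 (adjusted p = 0.105) and Pcna one of -0.19 ± 0.12 that turned to 0.10 under the macrophage scaling, which also moved the list's median from -0.24 to 0.07 (camera adjusted p = 0.000294; adjusted p = 0.435 with an estimated correlation). Of 16 interferon-stimulated genes 1 fell (1 adjusted over the list alone, 5 with the block). Their list had a median of -0.10, which became 0.18 under the macrophage scaling, and camera adjusted p = 0.0341 (adjusted p = 0.512 with an estimated correlation and 0.0947 under the macrophage scaling; 0.238, 0.115 and 0.117 without iron negative 5L and iron positive 3L and 3R). None of 15 dissociation and immediate early genes passed (none adjusted over the list alone), but 1 was higher and 9 lower with the block. The heat shock genes Hspa1b (8824 ± 2544 to 5626 ± 2037 CPM) and Hspa1a (8372 ± 2340 to 5325 ± 1943 CPM) had adjusted p = 0.172 and 0.159, and 0.0115 and 0.00869 with the block. These neighbours are nearly identical in sequence and their reads cannot be assigned with certainty. Camera called that list lower (adjusted p = 0.0166; adjusted p = 0.492 with an estimated correlation; 0.101 and 0.0524 without iron negative 5L and iron positive 3L). Skin epithelium, with 2 measured genes (Cdh1 at -0.33, adjusted p = 0.249, and Krt10 at 0.07, adjusted p = 0.901), and Schwann cells, with 2 (among them Mbp at -0.07, adjusted p = 0.703), held too few genes for a list test, and no adipocyte gene was measured. Without iron positive 4R, 7 mitochondrial genes and 1 interferon-stimulated gene of these lists passed. Without iron positive 5L, 4 interferon-stimulated, 3 dissociation and 2 proliferation genes were lower, and without iron positive 3R 1 dissociation gene was higher and 1 ribosomal and 1 proliferation gene lower. No gene passed in edgeR with any iron negative library left out.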

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

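The tests of explanations and of other groupings in this part were chosen after the results were seen, as were their bounds. Of 236 groups of 4 values examined (117 named genes and the library totals in each fraction), 5 had a library far from the other 3, or 2.1%, where chance gives about 5%. Bach1 stood at 139 CPM in iron negative 3L against 116 to 118 in the other iron negative libraries (gap over range 0.912). Me1 stood at 1.11 CPM in iron negative 3L against 2.65 to 2.78 (0.925). Hbb-bs stood at 25.9 CPM in iron negative 3R against 4.42 to 7.25 (0.868). Cd209g stood at 4.89 CPM in iron positive 3L against 0.53 to 0.76 (0.948), and Batf3 at 3.44 CPM in iron positive 4R against 6.70 to 7.28 (0.851).

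The first pattern weighed is the rise of stromal and muscle genes, stromal meaning the endothelial, the pericyte and the fibroblast and fibrosarcoma lists. Greater depth of the iron positive libraries cannot account for it, since levels are scaled to library size. The iron positive totals were also lower on average, at 21.21 M against 22.8 M, but after that scaling this says little more. No antibody sort that would remove other cells is named in the labels. The source may be vessel and muscle pieces trapped in the column, cells bound to iron-rich cells, or stromal cells that hold iron. The fibroblast and fibrosarcoma markers do not part stromal from malignant cells, so their rise may also come from the latter. None of these sources was tested.

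The second pattern is the rise of Ednrb. Were its reads all from endothelial or mural cells, its ratio to their 21 called markers would be as steady over the 4 iron positive libraries as theirs. Log2 of that ratio ranged over 5.4 units, against at most 2.63 for any of those markers. It also stayed above the largest range of the markers without each library, with the smallest value, 2.31 against 0.92, without 3L. The 21 markers were taken because they were called higher in these same libraries, which may favour steady ones, so these bounds may be too low. Were the Ednrb reads all from the cells that carry Hmox1, Slc40a1, Slc48a1 and Cd163, the ratio to those genes would vary as theirs do. It ranged over 2.08 units, against at most 1.4 for the 4 genes, but that rested on 5L alone, and without 5L it ranged over 0.45 units against 1.4. That source therefore stays open, as do a mixture of sources and a regulation of Ednrb that differs between tumors, which were not tested.

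The third pattern is the fall of MHC class II genes. A lower share of macrophages would lower them by about as much as macrophage markers, but 9 of the 10 lay more than 2 SD below the macrophage list's mean log2 fold change (-0.28, SD 0.20). Scaling was not excluded as part of the fall. Under the macrophage scaling the median of the class II list went from -1.02 to -0.71 and its genes past the threshold from 8 to 3. A lower class II level in the retained macrophages remains as a hypothesis, untested here, beside a shift among class II expressing cells such as B cells or dendritic cells, whose lists held 3 and 8 measured genes.

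Other groupings of the libraries were tried in the same tests. Since the tags pair the libraries, the fractions are set against the 8 groupings into 4 and 4 that part all 4 pairs, the real one included. These are too few for a share under 0.05. The fractions gave 1828 genes and the highest of the others 0 in edgeR, and 25 camera lists against 17, so 1 of the 8 reached the real value each time. In every other grouping each group holds libraries of both fractions, so the difference between fractions adds to the spread within groups. A low gene count there was likely from the start, and the contrast with 1828 says little. The groupings that keep a pair together, which mix the fractions and the tags, gave at most 0 genes in edgeR and 21 lists (35 groupings in all; at most 2048 genes at an unadjusted p under 0.05, against 4147 for the fractions). Camera with the preset correlation thus called many lists on groupings that cross the fractions, and a list call alone says little about iron.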

How the results depend on the processing

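The alternatives chosen after seeing the data were the macrophage scaling for the gene and list counts, camera without the stromal and muscle lists, and tags 3L and 5L alone. The others were chosen before the data were examined.

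The counts of 1133 higher and 695 lower genes became 1703 and 1070 with DESeq2, 189 and 273 with limma voom, 1705 and 1253 with the tag as a block, and 564 and 379 with a minimum of 5 CPM. On log2(TPM + 1) they were 413 and 205, on log2(TPM + 0.1) 706 and 270. Against 1.5-fold, 355 genes were higher and 0 lower in edgeR (70 lower at an unadjusted p under 0.05; DESeq2, against no change, called 1070). Library totals left 362 and length offsets 409 lower genes, with 1172 and 929 higher. The macrophage scaling gave 3198 and 36, and tags 3L and 5L alone 321 and 7. Leaving out libraries singly or by tag gave 0 to 1487 higher and 0 to 979 lower genes in the fits without the block. By tag, 489 and 55 remained without 3L, 568 and 84 without 3R, 708 and 430 without 5L, and 0 and 0 without 4R in edgeR (1486 and 1107 at an unadjusted p under 0.05; 836 and 361 with DESeq2). With the tag as a block, edgeR called 1228 and 314 without 3L, 1562 and 811 without 3R, and 1621 and 979 without 5L. Without 4R the blocked fit still called 723 higher and 219 lower genes. The cause of these changes was not tested.

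The iron panel's 5 higher genes became 1 with voom, 2 on log2(TPM + 1), 2 on log2(TPM + 0.1), 2 against 1.5-fold, 9 with the macrophage scaling, 1 on tags 3L and 5L alone, and 0 to 7 when libraries were left out. The 25 camera lists became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 8 with fry. They were 21 with the macrophage scaling, 21 without the 43 measured members of the stromal and muscle lists (all 25 but the 4 removed lists), and 17 to 25 when libraries were left out. Genes outside those lists, such as Col4a1, stayed in. The 21 calls therefore cannot tell whether stromal reads matter for the other lists.

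Over 117 named genes and 3007 combinations with a setting, 2073 were the same, 884 weaker, 31 stronger and 19 reversed. Under the macrophage scaling the sign turned for Bach1 (0.20), Ptgs2 (0.02), Tapbp (0.047), Vsir (0.018), Pcna (0.10), Rplp0 (0.093), Rpl4 (0.11) and Mbp (0.21). Krt10 turned to -0.086 with length offsets, -0.02 on log2(TPM + 1), -0.089 on log2(TPM + 0.1), -0.27 on tags 3L and 5L alone, and -0.078 to 0.219 when libraries were left out. Mbp ranged from -0.154 to 0.054 when libraries were left out, positive without iron positive 3R or both 3R libraries. Beyond the counts and calls given above, the block changed no other call in the fits on all libraries.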

Other observations

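The grouping in this part, and the comparison of 3L with 3R that it uses, were chosen after the data were seen. Of the 1133 genes called higher, 620 were above 2-fold higher in 3R than in 3L, 95 were above 2-fold higher in 3L than in 3R, and 418 lay within 2-fold. Among the genes with the largest ratio of 3R to 3L were Egfl7 (79.2 CPM in 3R and 2.89 in 3L), Abcc9 (31.2 in 3R), Mgp (42.5 and 2.19), Aqp1 (393 and 32.5) and the basement membrane collagen Col4a1 (1810 and 156). All 13 endothelial, all 8 called pericyte and all 7 called fibroblast markers were higher in 3R. Part of that gap was present in the iron negative libraries. There the endothelial and mural markers stood at -0.79 in 3L and 1.33 in 3R, against 2.94 and 6.26 in the iron positive ones, as log2 values less the iron negative mean. The called fibroblast markers stood at -0.65 and 1, against 1.27 and 4.52. Among the genes with the largest ratio of 3L to 3R, Ppbp stood at 361 CPM in 3L, 314 in 4R, 69.2 in 5L and 18.7 in 3R, and Cxcl3 at 166, 166, 45.5 and 13.9 CPM in the same order. F7, the coagulation factor that binds tissue factor, stood at 41.6, 44.4, 13.6 and 4.03 CPM, the chemokine Ccl6 at 1389, 1510, 489 and 226 CPM, and the lectin Clec4d at 301, 230, 97.8 and 51.4 CPM. In this group were Hmox1, Cd163, Marco, Arg1, Cd36, Gclm, Slc48a1 and the detoxifying enzymes Ptgr1 (195 and 30.9 CPM in 3L and 3R), Akr1b8 (150 and 34.1) and Mgst1 (56.4 and 15.8). For Hmox1, Slc40a1, Slc48a1 and Cd163 together the iron negative libraries stood at 0.07 in 3L and -0.34 in 3R, and the iron positive ones at 3.01 and 0.68. All 4 called heme genes, 5 called NRF2 targets and 4 called scavenger receptors were higher in 3L than in 3R. These genes were named after their values were seen.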
